A study of Mus musculus with 8 samples.

How the data were processed

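Gene expression was measured on 8 one-colour Agilent mouse arrays, each hybridised with Cy3-labelled cDNA from one RNA sample. The samples fall into 4 groups of 2: pulmonary single cells, which are the lung suspension before the fibroblasts were sorted from it, and A-type, B-type and C-type fibroblasts. Per the labels, the cells came from lungs of female C57BL/6 mice aged 12 to 16 weeks, 50000 cells were taken per sample, both samples of a group were prepared independently, and 10 ng of RNA was amplified for each array. The sort used antibodies against E-cadherin, CD45, CD31, TER119, CD146 and LYVE-1 as lineage markers and against PDGFRA, SCA-1 and THY-1. Which combination of PDGFRA, SCA-1 and THY-1 defines each fibroblast type is not given in the sources used here, nor is the number of mice behind a sample. Arrays are named by group and replicate below: Pu1 and Pu2 for the pulmonary single cells, then A1, A2, B1, B2, C1 and C2.

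Per the file headers, the scanner files hold background-subtracted intensity for each spot from Agilent Feature Extraction 10.10.1.1, and this processed signal was the starting point. The authors' value table holds log2 values with no stated scaling. Set against the scanner values, each of its columns equalled the log2 of the processed signal minus one constant, within 0.02 for 100% of the 55653 probes compared, and every column had a median of 4.84. The table therefore differs from median scaling only by a constant, and no part of its scale, centring or direction stays unknown. It served as an alternative.

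Each array carries 62976 spots, of which 59305 are not controls and belong to 55681 probes. Spots of 432 probes printed more than once were averaged, 28 probes with a spot called an outlier on at least 1 array were left out, and 0 values were saturated. Probes were named through the mouse RefSeq table: 28026 by the accession in the file, 321 by another RefSeq accession listed for the probe and 265 by a synonym, while 5037 kept the symbol in the file. A further 22032 probes stayed without a gene name. Accessions of several genes were listed for 818 of all kept probes, named or not. Probe coordinates in the files belong to an older mouse assembly than the naming table and were not used here.

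The log2 processed signal of each array was scaled by subtracting the array's 75th percentile. A probe was kept when it was well above background, by the scanner software's own call, on both arrays of at least 1 group, and the brightest kept probe over all arrays stood for its gene. This left 17653 of the 24304 named genes on the array. Testing used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with all 8 arrays in one fit of the 4 group means, so that the groups share one estimate of the spread (4 residual and 3.06 prior degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The 7 comparisons were the mean of the 3 fibroblast types minus pulmonary single cells, each type minus pulmonary single cells, and the 3 differences between types. From the last 3, sets of genes higher in one type than in both others were taken. A change is given as a log2 difference with the standard error (SE) of the fit, and each group mean rests on 2 arrays, which limits the precision. Figures were drawn with matplotlib 3.10.9, and files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

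Where a probe was not well above background on any array of the dimmer group, its fold is a bound, written "at least". It sets the mean of the brighter group against, per array, the higher of the dim probe's own signal and the lowest signal well above background, averaged over the dimmer group's arrays. In the mean of the 3 fibroblast types, a fold is a bound when this holds for at least 1 type, and every fibroblast array that was not above background is then treated this way. Where only some arrays of the dimmer group measured a gene, its fold uses all of them as they stand, and the value "with the floor" sets the other arrays no lower than that lowest signal. It is given where it is lower by over 1.5 times, and for some other genes. Different probes of a gene were not averaged, and disagreement between them is stated where such a gene is named.

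The comparisons, the tests, the gene lists, the rule for the genes that are named and all alternatives other than those marked as added later were fixed before the data were examined. The lists come from general knowledge of published markers. A study of lung fibroblast subtypes that may include these samples was recalled while they were written, with Cd248 and Itga8 as its markers, so the place of these 2 genes in the adventitial and alveolar lists is not independent of it. Named genes are the 9 genes of the sorting panel, the 10 highest and 10 lowest called genes of a comparison among those separated on all arrays, well above background in the brighter group and carrying a plain symbol, the 8 leading genes of each type set under the same conditions, and up to 4 members of each list. The 34 lists cover the sorting panel's positive and lineage markers; blood endothelial, lymphatic endothelial, alveolar epithelial type 1 and type 2, airway epithelial, macrophage and dendritic, T and NK, B, neutrophil, erythroid and platelet, mesothelial, smooth muscle, pericyte, Schwann and cartilage cell markers; fibrillar collagens, elastic fibre, small leucine-rich proteoglycan and basement membrane genes; adventitial, alveolar and myofibroblast or peribronchial fibroblast markers; lipid storage, retinoid metabolism, complement, chemokine and cytokine, Wnt, BMP and TGF-beta, and FGF, HGF and hedgehog genes; mesenchymal transcription factors; dissociation and immediate early genes; and proliferation genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all 238 tests of 34 lists in 7 comparisons. Camera called 127 of them. With the correlation estimated from the data, 0 of the 238 were called, the lowest adjusted p being 0.0971. Fry, which tests each list by itself and not against other genes, called 153. Counts of called members are given over all genes and adjusted over the list alone.

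The lists' members absent from the array by name were Ccl21a, Ighm and Hspa1b. Listed genes not well above background in any group, and so not tested, included Grem1, Gfra3, Wnt2, Frzb, Col2a1, Matn1, Cnmd, Cfd, Gp9, Bnc1, Aurkb, Cenpf, Lmod1 and Myocd. Results of the Schwann cell list and of some other list members are not reported here.

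The fit was tested on simulated data with group-specific spread, 200 seeded genes in each of 5 simulations per comparison. In the mean-of-types comparison, 64% of 4-fold and 90.8% of 8-fold changes were recovered. Between types, 34.8% to 38.4% of 4-fold and 81.6% to 83.6% of 8-fold changes were recovered. False calls made up 23.5% of simulated calls in the mean-of-types comparison and 24.7% in C-type minus pulmonary single cells, above the nominal 5%. They made up 7.58% and 8.16% for A-type and B-type minus pulmonary single cells, 3.62% for A minus C, 3.6% for B minus C and 0% for A minus B. These shares hold for 200 changed genes among 17653. Far more genes passed in the real comparisons with pulmonary single cells, while 0 passed between A and B and 73 between A and C. Recovery at an adjusted threshold depends on how many genes change. Neither the shares nor the recoveries therefore need carry over to the real comparisons, between types or with pulmonary single cells.

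Both pulmonary arrays lie on slide 1 and were scanned together, and all 6 fibroblast arrays lie on slide 2 and were scanned together. Slide and scan therefore cannot be told apart from the difference between pulmonary single cells and fibroblasts, whereas the differences between fibroblast types lie within one slide. The alternatives were normexp background correction (offset 50), quantile and median scaling, the percentile over probes above background on all arrays, the authors' table, no filter and a stricter filter on dim probes, every probe or the mean of a gene's probes, array weights, trended robust variance, a fold of at least 2, the replicate number as a block, the compared arrays alone, and each array left out in turn. Both the 6 fibroblast arrays alone and the list tests with each array left out were added after seeing the data. Spike-in and other control spots were not analysed here.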

Results

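Gene expression was measured with one-colour arrays in pulmonary single cells and in the A-type, B-type and C-type fibroblasts sorted from them, with 2 independently prepared samples in each of the 4 groups. Signal at the 75th percentile of the probes was 128 and 260 units on the pulmonary arrays Pu1 and Pu2, 187 and 188 on A1 and A2, 180 and 169 on B1 and B2, and 141 and 113 on C1 and C2. The share of spots well above background was 68.7% on both pulmonary arrays, 66.4% on A1, 60.6% on A2, 60.7% on B1, 63.4% on B2, 60.6% on C1 and 54.6% on C2. Over the 17653 genes tested, arrays of one group correlated at 0.985 in the A type, 0.985 in the B type, 0.947 in the C type and 0.915 in the pulmonary single cells. The share of genes at least 2-fold apart between the arrays of a group was 5.19% in A, 5.49% in B, 20.8% in C and 31.5% in the pulmonary single cells. Pulmonary and fibroblast arrays correlated at 0.749 to 0.797. These correlations are across genes, which are not independent replicates.

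**Figure D1:**
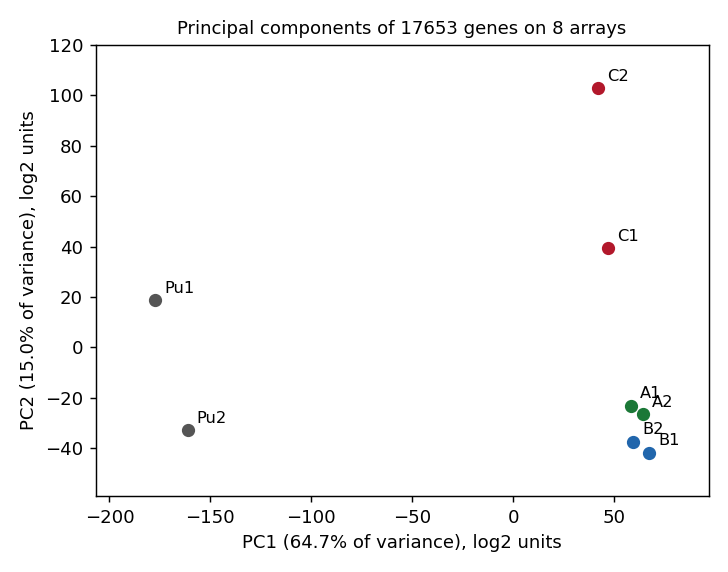
Principal components of 17653 genes on the 8 arrays, with the first component on the horizontal axis and the second on the vertical axis, both in log2 units; each point is an array coloured by group. The first component (64.7% of the variance) separates both pulmonary arrays from the 6 fibroblast arrays, and the second (15.0%) separates the C-type arrays from the A-type and B-type arrays and C1 from C2.

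The first comparison set the mean of the 3 fibroblast types against the pulmonary single cells, which asks what the sort kept and what it removed. Genes of the fibroblast matrix were brighter in the sorted cells, led by lumican (Lum), a collagen-binding proteoglycan, at 58.5-fold (log2 difference 5.87 ± 0.46 SE, adjusted p = 0.000128). Pdgfra, the receptor targeted in the sort, was 4.56-fold higher (2.19 ± 0.22, adjusted p = 0.000415). Genes of leukocytes, endothelium and epithelium were dimmer in the fibroblasts. Chil3, a chitinase-like protein of alveolar macrophages, was 3055-fold lower (-11.58 ± 0.92, adjusted p = 0.000145; 2180-fold with the floor) and was well above background on 4 of the 6 fibroblast arrays. Tyrobp, an adaptor of myeloid receptors, was 1081-fold lower (1009-fold with the floor) and above background on 3 of the 6.

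The surface proteins of the sorting panel were read through their genes. Because the sort used these proteins, the values of their genes are not independent of it, between types as well. Among the lineage markers, Lyve1, a hyaluronan receptor of lymphatic endothelium, was at least 107-fold lower in the fibroblasts (-8.45 ± 0.43, adjusted p = 3.42e-05), and Pecam1, which encodes CD31, was 66.4-fold lower (-6.05 ± 0.38, adjusted p = 5.92e-05) with 1 of the 2 C-type arrays not above background. Cdh1, which encodes E-cadherin, was at least 4.34-fold lower, and Ptprc, which encodes CD45, was 5.13-fold lower (-2.36 ± 0.27, adjusted p = 0.000747). Mcam, which encodes CD146, did not pass (-0.27), and its probes disagreed: its other probe, dimmer in every array, had a mean of -0.73 in the pulmonary cells and was above background on 0 fibroblast arrays. With the mean of a gene's probes, which takes in these background readings, Mcam passed as lower (adjusted p = 0.00104), and the size of that difference is not measured. The sign of the Mcam value also turned under median scaling (0.0921). Camera put the lineage markers lower (4 lower of 5, adjusted p = 0.000291; adjusted p = 0.0971 with an estimated correlation).

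Among the positive markers, 1 of 3 passed (camera adjusted p = 0.689; the median was below 0 and the mean and the test above it). Ly6a, which encodes SCA-1, had mean scaled log2 signals of 4.97 in the pulmonary cells, 6.22 in A, 6.71 in B and 1.79 in C, and did not pass between fibroblasts and pulmonary cells (-0.07, adjusted p = 0.936; 0.29 under median scaling, 0.02 without Pu2, 0.33 without C2). Thy1 had means of 2.85, -0.24, 4.82 and 0.17 in the same order (difference -1.27, adjusted p = 0.248), and passed without C1 (-1.84, adjusted p = 0.00344). The C-type arrays differed from each other in both genes, with Ly6a at 2.96 on C1 and 0.61 on C2 and Thy1 at 1.89 on C1 and -1.56 on C2.

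**Figure D2:**
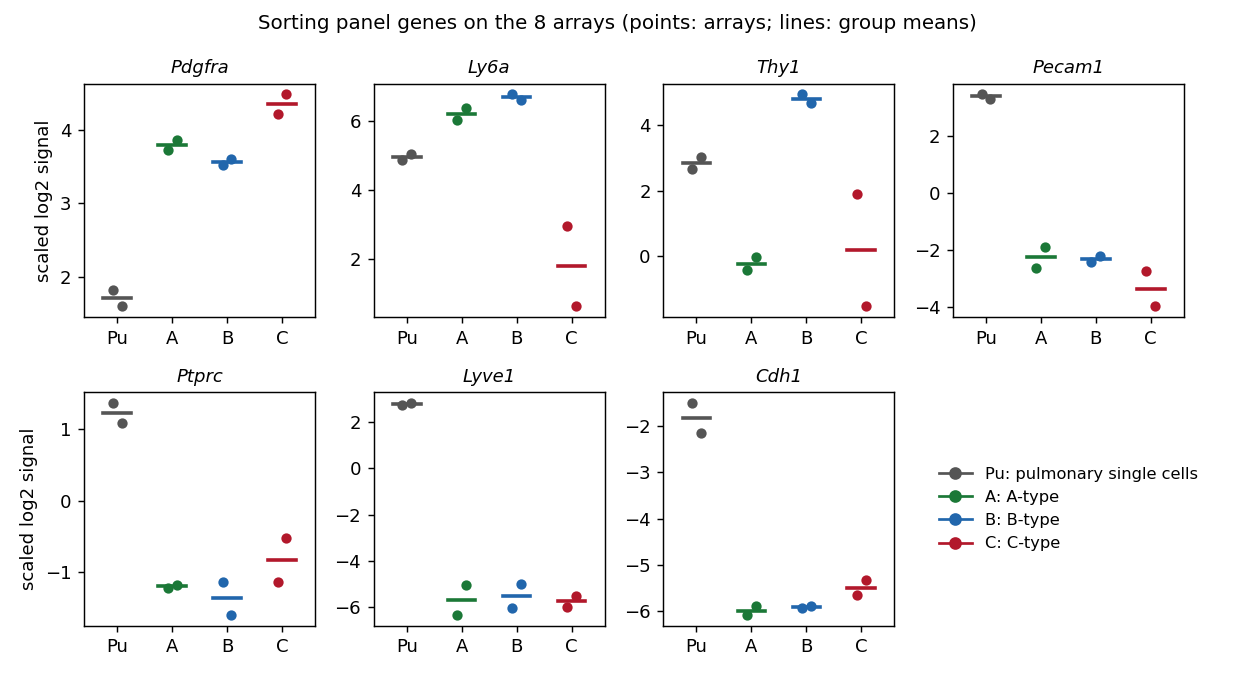
Scaled log2 signal of 7 sorting panel genes (vertical axes) in the 4 groups (horizontal axes); points are arrays and lines are group means. Pdgfra lies between 3.53 and 4.48 on the fibroblast arrays against 1.82 or lower on the pulmonary arrays, Thy1 is brightest on the B-type arrays, and Ly6a and Thy1 differ between C1 and C2.

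Markers of other lung cell types were lower in the fibroblasts. All 12 blood endothelial genes were lower (adjusted p = 9.39e-09; adjusted p = 0.0971 with an estimated correlation), among them the adhesion gene Cdh5 at 372-fold (238-fold with the floor), above background on 3 of 6 fibroblast arrays, and Cldn5 at 180-fold, above background on 5 of 6. Of 4 lymphatic genes 3 were lower, such as Flt4 at least 21.1-fold (adjusted p = 0.00162; adjusted p = 0.102 with an estimated correlation). Of 9 alveolar type 2 genes 8 were lower, and 9 when adjusted over the list alone, with the surfactant gene Sftpc at 196-fold and Sftpa1, above background on 3 of 6 fibroblast arrays, at least 196-fold (adjusted p = 1.10e-06; adjusted p = 0.0971 with an estimated correlation). Among 8 alveolar type 1 genes 7 were lower, such as Hopx at 14.6-fold, and Pdpn, which lymphatic and mesenchymal cells also express, was 6.8-fold higher (adjusted p = 0.000239; adjusted p = 0.0971 with an estimated correlation). The airway list had 13 of 14 lower, and 14 over the list alone, with the club cell secretoglobin Scgb1a1 at 317-fold (adjusted p = 1.41e-08; adjusted p = 0.0971 with an estimated correlation). Mesothelial genes were lower in 4 of 5, and 5 over the list alone, with Msln at least 8.47-fold (adjusted p = 0.000501; adjusted p = 0.119 with an estimated correlation).

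Blood cell markers were lower as well. Of 14 macrophage and dendritic genes 13 were lower, including the lysozyme gene Lyz2, above background on 1 fibroblast array, at least 532-fold and the class II gene H2-Aa at least 372-fold (adjusted p = 6.73e-11; adjusted p = 0.0971 with an estimated correlation). T and NK genes were lower in 10 of 11, and 11 over the list alone, with Il2rb at 91.9-fold, above background on 4 of 6 fibroblast arrays (adjusted p = 1.61e-07; adjusted p = 0.0971 with an estimated correlation). All 6 B cell genes were lower, with Cd79a at 16.8-fold (adjusted p = 2.96e-05; adjusted p = 0.0976 with an estimated correlation). Of 8 neutrophil genes 5 were lower, with S100a8, above background on 1 fibroblast array, at least 112-fold (adjusted p = 0.000274; adjusted p = 0.0976 with an estimated correlation). All 8 erythroid and platelet genes were lower, with the globin gene Hba-a1 at 237-fold (adjusted p = 2.59e-06; adjusted p = 0.0971 with an estimated correlation).

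Markers of other mesenchymal cells moved both ways or did not pass as lists. Of 8 smooth muscle genes, 3 were lower, and 4 over the list alone, such as the myosin gene Myh11 at 9.64-fold, and Smtn was 4.33-fold higher (2.11; 1.45 without Pu1, 2.77 without Pu2; list adjusted p = 0.0785). Pericyte genes split into 3 higher, among them the potassium channel gene Kcnj8 at 13.4-fold, and 4 lower, or 5 over the list alone, among them Rgs5 at least 5.38-fold (list adjusted p = 0.337). Cartilage genes were higher in 2 of 3, Comp at least 8.29-fold and the transcription factor gene Sox9 at 8.95-fold, above background on 5 of 6 fibroblast arrays (list adjusted p = 0.179).

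Matrix genes were higher in the sorted fibroblasts. Among fibrillar and beaded-filament collagens 11 of 12 were higher, and 12 over the list alone, such as Col16a1 at 17.7-fold and Col5a1 at 13.4-fold (adjusted p = 1.08e-07; adjusted p = 0.124 with an estimated correlation). Of 18 elastic fibre and microfibril genes 15 were higher, among them elastin (Eln) at 9.83-fold and Fbln5 at 13.4-fold, and 1 was lower, Fbn2 at 1.72-fold (adjusted p = 2.01e-07; adjusted p = 0.195 with an estimated correlation). Small leucine-rich proteoglycans were higher in 8 of 10, with decorin (Dcn) at 20.1-fold, and Chad, above background on 5 of 6 fibroblast arrays, was 3.7-fold lower (adjusted p = 0.000268; adjusted p = 0.102 with an estimated correlation). Of 18 basement membrane genes 12 were higher, with Col15a1 at 16.9-fold, and 1, or 2 over the list alone, was lower, Lama5 at 7.76-fold (adjusted p = 0.00076; adjusted p = 0.177 with an estimated correlation).

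Fibroblast markers known from other work were also higher in part. Of 18 adventitial fibroblast markers 15 were higher, such as the hyaluronan synthase gene Has1 at 27.7-fold and the chemokine gene Ccl11 at 30.8-fold, and 3 were lower, Dpp4, Sema3c and Anxa3 (-3.26, -1.08 and -1.43; adjusted p = 1.71e-06; adjusted p = 0.203 with an estimated correlation). Alveolar fibroblast markers were higher in 6 of 13, and 7 over the list alone, with the transcription factor gene Tcf21 at 4.27-fold, and Ces1d was lower (list adjusted p = 0.0864). Myofibroblast and peribronchial markers were higher in 4 of 10, with Hhip, an inhibitor of hedgehog signalling, at 7.56-fold (2.92; 2.33 without Pu1, 3.51 without Pu2; list adjusted p = 0.0976). Lipid storage genes were lower in 9 of 13, and 10 over the list alone, with the fatty acid transporter gene Cd36, above background on 1 fibroblast array, at least 277-fold, and Fgf10, a growth factor of the lung mesenchyme, was 10.0-fold higher (adjusted p = 0.00127; adjusted p = 0.102 with an estimated correlation). Of 11 retinoid genes 4 were higher, including Rbp4 at 33-fold (5.05 ± 0.29), and Rarb was lower (-1.35, adjusted p = 0.0487) while its other 2 probes had a median of 0.97. The Rarb call was lost without Pu1 (-0.55) and without every fibroblast array, and kept without Pu2 (-2.15). The retinoid list did not pass (adjusted p = 0.49).

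Signalling and regulatory genes were mostly higher. All 10 complement genes were higher, such as C1s1 at 15.5-fold (adjusted p = 1.15e-06; adjusted p = 0.102 with an estimated correlation). Of 18 chemokine and cytokine genes 12 were higher, and 13 over the list alone, with Cxcl1 at 25.2-fold and Il6 at 18.3-fold, and Cxcl2 was 23.7-fold lower, above background on 5 of 6 fibroblast arrays (adjusted p = 0.00304; adjusted p = 0.204 with an estimated correlation). Wnt genes were higher in 9 of 14, with the secreted antagonist Sfrp1 at 7.7-fold (adjusted p = 0.000139; adjusted p = 0.0971 with an estimated correlation). BMP and TGF-beta genes were higher in 12 of 16, with Tgfb3 at 15.6-fold, and lower in 4, with Bmp6, above background on 4 of 6 fibroblast arrays, at least 23.5-fold (adjusted p = 0.00695; adjusted p = 0.119 with an estimated correlation). FGF, HGF and hedgehog genes were higher in 11 of 18, with Igf1 at 14.6-fold (adjusted p = 0.00104; adjusted p = 0.0971 with an estimated correlation). Mesenchymal transcription factors were higher in 15 of 19, with Prrx1 at 18.3-fold and Meox2 at 17.4-fold (adjusted p = 6.87e-06; adjusted p = 0.0971 with an estimated correlation). Dissociation and immediate early genes were higher in 8 of 11, with Egr1 at 3.75-fold (adjusted p = 0.000361; adjusted p = 0.176 with an estimated correlation). Proliferation genes were lower in 6 of 10, and 9 over the list alone, with Mki67 at 17-fold (adjusted p = 0.000268; adjusted p = 0.165 with an estimated correlation).

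**Figure D3:**
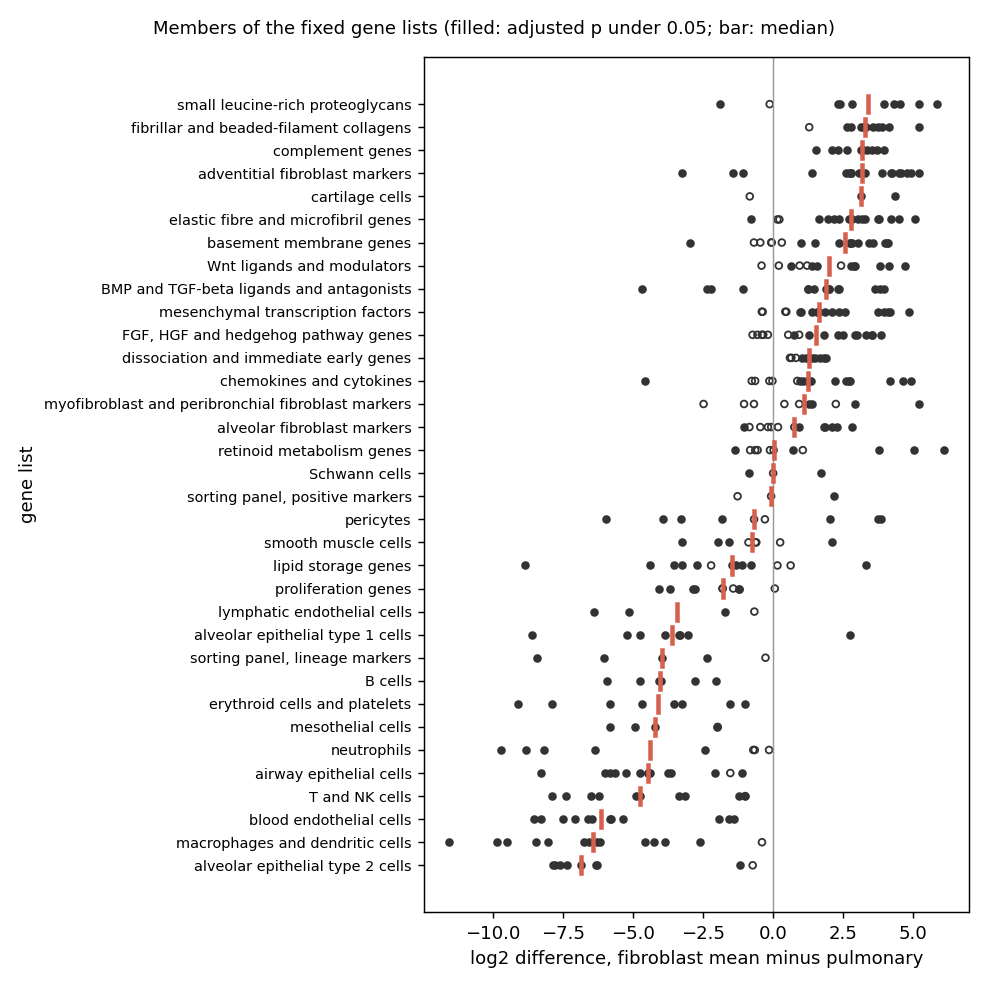
Log2 difference between the mean of the 3 fibroblast types and pulmonary single cells (horizontal axis) for the tested members of the 34 fixed lists (vertical axis); filled points passed the adjusted p of 0.05, open points did not, and bars are list medians. List medians range from -6.86 for alveolar type 2 markers to 3.39 for small leucine-rich proteoglycans.

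In all, 6458 genes passed, 3598 higher and 2860 lower in the fibroblasts (55.7% higher). The genes with the greatest differences upward among those named by rule were Nrg2, a neuregulin, at least 49.3-fold, Mgarp at least 19.4-fold, Arhgap36 at least 19.2-fold, Fbln7 at 50.1-fold, and, each above background on 1 pulmonary array, Wasf1 (6.31; 5.07 without Pu1, 7.55 without Pu2), Hoxc4 (5.95; 8.45 without Pu1, 3.45 without Pu2), Tceal5 (5.81; 4.34 without Pu1, 7.28 without Pu2), Dner (5.57; 6.49 without Pu1, 4.64 without Pu2) and Lonrf2 (5.51; 3.73 without Pu1, 7.28 without Pu2). With the floor these 5 were 5.32, 4.80, 4.84, 5.47 and 4.43. Downward they were, beside Chil3, Tyrobp, Lyz2 and H2-Aa, the leukocyte genes Ctss, above background on 3 of 6 fibroblast arrays, at least 801-fold, Laptm5 at least 521-fold, Cybb at least 371-fold, S100a9, above background on 1 fibroblast array, at least 283-fold (-9.73, with -10.50 without Pu1 and -8.97 without Pu2) and Clec7a at least 194-fold, and Atp6v0d2, a proton pump subunit, at least 352-fold. Of the 139 named genes that passed, 34 moved by over 1.5 times when Pu1 or Pu2 was left out, and 5 lost their call without Pu1. The split of calls moved with the scaling, to 71.6% higher under median scaling, which shifts the median of all genes by 0.36, to 71.7% in the authors' table (0.36), and to 39.2% with the percentile over probes above background on all arrays (-0.31). It was 70.7% with the stricter filter, which tests fewer genes (0.16). With array weights 3103 genes passed, and with every probe tested 10264 probes did, among them probes without a gene name. Slide and scan cannot be told apart from this comparison.

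Each fibroblast type was also set against the pulmonary single cells. Lum was higher in all 3 types, by 6.29 ± 0.56 in A, 7.05 ± 0.56 in B and 4.27 ± 0.56 in C (3.50 without C1, 5.04 without C2), and Meox2, a homeobox gene of the mesenchyme, by 4.35, 3.97 and 4.06. Pdgfra was 4.23-fold, 3.61-fold and 6.2-fold higher. Thy1 passed in none of the 3 types in the main fit, with log2 differences of -3.09 in A and 1.97 in B. It passed in A and B without C1 or without C2, and in C without C1 (-4.40, resting on C2 alone). With the 4 compared arrays alone it passed in A and B (limma adjusted p = 0.00589 and 0.0197). Under normexp correction it passed as lower in A and C and as higher in B (limma adjusted p = 0.0111, 0.0316 and 0.04). In A Thy1 also passed under quantile scaling and the percentile over probes above background on all arrays (limma adjusted p = 0.0395 and 0.0402). The stricter filter and trended robust variance gave the same call in A (limma adjusted p = 0.04 and 0.0327). Ly6a passed in C alone, where it was lower (-3.18 ± 0.68, adjusted p = 0.0141; -4.36 without C1, -2.01 without C2), and its call was lost without Pu2 (-3.09), with array weights (adjusted p = 0.059) and with the 4 compared arrays alone (0.0555). The A-type and B-type differences of 1.25 and 1.74 did not pass, and passed without C1 or without C2 (adjusted p = 0.0212 and 0.0067), the B-type one also under normexp correction (0.0429) and with the 4 compared arrays alone (0.0235). Npnt, a basement membrane ligand of an integrin that alveolar fibroblasts express, was lower in B (-3.45 ± 0.30, adjusted p = 0.000349) and higher in C (2.60 ± 0.30, adjusted p = 0.0012), and in A it did not pass (-0.51, adjusted p = 0.258). Adventitial markers were higher in 15 of 18 in A, 14 in B and 12 in C (adjusted p = 3.03e-07, 1.92e-09 and 0.000244; adjusted p = 0.19, 0.149 and 0.299 with an estimated correlation; 15, 14 and 12 over the list alone), with 1, 0 and 3 lower. Alveolar fibroblast markers were higher in 5 of 13 in A, 4 in B and 8 in C (6, 6 and 10 over the list alone), with 1, 4 and 0 lower (adjusted p = 0.151, 0.798 and 8.64e-06; the last was adjusted p = 0.0971 with an estimated correlation).

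In these comparisons 4690 genes passed in A (2611 higher), 5140 in B (2862 higher) and 5025 in C (2604 higher). Genes higher in all 3 types numbered 1745 and genes lower in all 3 numbered 1564. Independent lists of these sizes would share 62.4 and 36.8. In 20 simulations of unchanged groups against the same controls, with equal spread in all groups, 0 genes were called in all 3. That count cannot bear on the overlap, because the adjusted threshold leaves few or no calls where nothing changed. In 20 other simulations, with each group's own spread, the same numbers of leading genes shared a mean of 1109 and 894 (at most 1139 and 931). Calls in all 3 were not counted in these. The pulmonary arrays are too few to split, so part of the overlap may come from the shared controls. Without A1 2411 genes passed in A and without A2 2157, and without B1 2346 passed in B and without B2 2479. In C 2265 passed with the 4 compared arrays alone. With array weights the counts were 3120, 3389 and 2143. Median scaling moved the share of higher calls from 55.7% to 68.3% in A, from 55.7% to 69.7% in B and from 51.8% to 69.2% in C, with median shifts of 0.33, 0.35 and 0.40. The percentile over probes above background on all arrays moved it to 41.4%, 38.7% and 35.9%, with shifts of -0.29, -0.32 and -0.31.

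A-type and B-type fibroblasts were compared next, to ask how the types differ. No single gene passed: limma called 0 of 17653 at the adjusted threshold, 573 had an unadjusted p under 0.05 and the lowest adjusted p was 0.138. Camera called 5 of the 34 lists. Adventitial markers as a list were lower in A (adjusted p = 5.15e-08; adjusted p = 0.176 with an estimated correlation), with 0 of 18 members called and 4 lower over the list alone, such as Pcsk6, a proprotein convertase gene (-1.56 ± 0.27), and Sema3c, a semaphorin gene (-1.48 ± 0.29). Alveolar markers as a list were higher in A (adjusted p = 1.41e-09; adjusted p = 0.0971 with an estimated correlation), with 0 of 13 called and 4 higher over the list alone, such as Npnt (2.94 ± 0.30, adjusted p = 0.149) and Itga8, an integrin subunit gene (2.52 ± 0.35, adjusted p = 0.218).

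The other 3 lists that passed between A and B each had 0 members called and 1 over the list alone. Retinoid genes were higher in A (adjusted p = 0.0153; adjusted p = 0.131 with an estimated correlation), with Aldh1a1, a retinaldehyde dehydrogenase gene, at 1.34 ± 0.31. The call was lost without B2 (adjusted p = 0.0582). Mesenchymal transcription factors were higher in A (adjusted p = 0.0177; adjusted p = 0.128 with an estimated correlation), with Tbx2 at 1.61 ± 0.31. The call was lost without A2, B2 or C1 (highest adjusted p = 0.102). Myofibroblast and peribronchial markers were lower in A (adjusted p = 0.0485; adjusted p = 0.203 with an estimated correlation), with Aspn at -1.84 ± 0.28. The call was lost without A2, B1, Pu1 or Pu2 (highest adjusted p = 0.188), and under quantile scaling (0.0698), median scaling (0.0642) and the replicate block (0.0702). The adventitial and alveolar calls held with each of the 8 arrays left out, with a highest adjusted p of 1.47e-05 and 4.39e-07. Thy1 was -5.06 ± 0.97 between A and B (adjusted p = 0.257), and passed under normexp correction and with array weights (adjusted p = 0.0405 and 0.0069). By gene, 244 passed with array weights, 21 with normexp, 4 with trended robust variance and 0 with each array left out.

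A-type fibroblasts differed from C-type fibroblasts in 73 genes, 51 higher and 22 lower in A. Higher in A were Efhd1, a mitochondrial calcium-binding protein gene, at least 21.0-fold (5.36 ± 0.54, adjusted p = 0.027), the chemokine gene Ccl8 at least 21.7-fold (5.10 ± 0.33, adjusted p = 0.0188) and Aldh1a2, a retinoic acid synthesis gene, at 20.1-fold (4.33 ± 0.60, adjusted p = 0.0465). The SCA-1 relatives Ly6c1 and Ly6g were 16.3-fold and 18-fold higher. Ly6a itself did not pass (4.43 ± 0.68, adjusted p = 0.0584), nor did Ly6f (4.96, adjusted p = 0.0686). Ly6a passed without C1 (5.61, adjusted p = 0.00832) and under normexp correction, the stricter filter, array weights and trended robust variance (adjusted p = 0.0101, 0.0431, 0.0231 and 0.0271). Higher in C were Upk1b, a tetraspanin of urothelium and mesothelium, at least 13.3-fold (-4.57 ± 0.40, adjusted p = 0.027), Chd7, a chromatin remodeller gene, at least 4.59-fold and Npnt at 8.62-fold (-3.11 ± 0.30, adjusted p = 0.027).

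Other genes higher in A by the naming rule were Lrrn4cl at 33.4-fold (5.06, or 4.32 with the floor), measured on 1 of the 2 C-type arrays like Ly6g, Lsamp at least 11-fold, Rbm24 at least 6.88-fold, Lmx1a at least 6.49-fold and Nipal3 at least 4.33-fold. Others lower were Tcim, Dach1, Mtss1 and Vipr2 at 8.86-fold, 8.85-fold, 8.31-fold and 8.13-fold, and Adgrg6, Sytl2 and Mx1 at least 8.32-fold, 5.48-fold and 3.18-fold. Without C1 and without C2 the differences were 6.23 and 4.49 for Efhd1, 6.05 and 4.07 for Lrrn4cl, 5.33 and 3.33 for Aldh1a2, 5.09 and 3.72 for Lsamp, 4.72 and 3.33 for Ly6c1 and 4.54 and 2.86 for Fgf18. Sytl2 was -2.90 without A1 and -4.50 without A2.

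Adventitial markers were higher in A as a list (adjusted p = 1.92e-09; adjusted p = 0.149 with an estimated correlation), with 3 of 18 called, Pcsk6 at 5.66-fold, Cd248 at 5.48-fold and Sema3c at 4.35-fold, and 13 higher and 2 lower over the list alone. Alveolar fibroblast markers were lower (adjusted p = 1.61e-07; adjusted p = 0.0971 with an estimated correlation), with Npnt called among 13 and 6 lower over the list alone. Wnt genes were higher (adjusted p = 0.000243; adjusted p = 0.0971 with an estimated correlation), with Sfrp4 at 6.46-fold the called member of 14 and 7 over the list alone. Chemokines were higher (adjusted p = 0.00063; adjusted p = 0.177 with an estimated correlation), with Ccl8 called and 4 over the list alone. Myofibroblast and peribronchial markers were higher (adjusted p = 0.00703; adjusted p = 0.141 with an estimated correlation), with Fgf18 called at 13-fold, measured on 1 C-type array, and 2 over the list alone. Complement genes passed as a list (0.59, adjusted p = 0.0376; adjusted p = 0.316 with an estimated correlation), with 0 of 10 called, and not without A1 (adjusted p = 0.0681), C1 (0.0893) or C2 (0.0984), nor under quantile scaling (0.0742).

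Markers of alveolar type 2 epithelium were lower in A than in C as a list (adjusted p = 0.00169; adjusted p = 0.169 with an estimated correlation), with 0 of 9 members called and 4 lower over the list alone, among them Sftpc at -2.51 ± 0.61 (adjusted p = 0.154). This stands beside each list above that was higher or lower in C. The other list calls between A and C held with each array left out (highest adjusted p = 0.0403). The gene calls did not: 0 genes passed without A1, A2, B1, B2 or C2, 483 passed without C1, and 229 passed without Pu1 or without Pu2. With the 6 fibroblast arrays alone, all on one slide, 229 passed. Between types this is the same fit as without Pu1 or without Pu2, because a lone array adds nothing to the estimate of the spread. It is not a separate check. With the 4 compared arrays alone 0 passed, with the replicate number as a block 0, and without the filter on dim probes 1.

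B-type fibroblasts differed from C-type fibroblasts in 425 genes, 220 higher and 205 lower in B. Higher in B were Efhd1 at least 177-fold (8.44 ± 0.54, adjusted p = 0.0029), Dpp4, a surface peptidase gene of adventitial fibroblasts, at 56.7-fold (5.83 ± 0.68, adjusted p = 0.00897; 28.4-fold with the floor) and Plau, which encodes urokinase, at 62.4-fold (5.96 ± 0.74, adjusted p = 0.0109; 31.8-fold with the floor). Ly6a was 30.3-fold higher in B (4.92 ± 0.68, adjusted p = 0.0168), a call lost without B1 or B2 (adjusted p = 0.142 and 0.127) and with the 4 compared arrays alone (0.103). Higher in C were Prom1, a membrane glycoprotein gene, at least 52.9-fold (-6.82 ± 0.76, adjusted p = 0.00748), Npnt at 66.2-fold (-6.05 ± 0.30, adjusted p = 0.0018), and the adrenergic receptor gene Adra1a at 46.9-fold (-5.55 ± 0.41, adjusted p = 0.00319). Thy1 did not pass (4.65 ± 0.97, adjusted p = 0.0633), and passed without C1 (6.38) or without C2 (2.93), and under normexp correction, the stricter filter, array weights and trended robust variance (adjusted p = 0.00699, 0.0419, 0.0212 and 0.0328).

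Further genes higher in B were Lrrn4cl and Ly6f at 83.5-fold and 47.3-fold (49.9-fold and 30.2-fold with the floor), measured like Dpp4 and Plau on 1 of the 2 C-type arrays, and Cmah, Ccl8, Aif1l, Lmx1a and Smpd3 at least 38.1-fold, 29.0-fold, 26.6-fold, 15.6-fold and 12.5-fold. Further genes lower in B were the connexin gene Gja5 at 34.2-fold and Scn3a, Nebl, Shisal1, Il34, Upk1b and St8sia4 at least 43.2-fold, 34.6-fold, 26.3-fold, 22.9-fold, 15.2-fold and 9.82-fold. Without C1 and without C2 the differences were 9.30 and 7.57 for Efhd1, 7.37 and 5.39 for Lrrn4cl, 7.25 and 4.68 for Plau, 7.07 and 4.05 for Ly6f, 6.88 and 4.77 for Dpp4, 6.55 and 5.17 for Aif1l and 6.10 and 3.74 for Ly6a. Without B1 and without B2 they were -5.82 and -7.82 for Prom1 and -5.63 and -4.32 for Il34.

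Adventitial markers were higher in B (adjusted p = 1.49e-11; adjusted p = 0.119 with an estimated correlation), with 8 of 18 called higher and Hsd11b1, a glucocorticoid-activating enzyme gene, called lower (-1.70), and 16 higher and 1 lower over the list alone. Beside Dpp4 they included Pcsk6 at 16.7-fold and Anxa3 at 15.4-fold, both measured on 1 C-type array, and the alarmin gene Il33 at 13.4-fold. Alveolar fibroblast markers were lower in B (adjusted p = 4.63e-11; adjusted p = 0.0971 with an estimated correlation), with 6 of 13 called lower and 10 over the list alone, among them Itga8 at 30.2-fold, Limch1 at 10.2-fold and Ces1d at 5.63-fold. These calls held with each array left out, with highest adjusted p values of 4.51e-09 and 1.77e-07. Il33 was 4.51 without C1 and 2.99 without C2, and Anxa3 4.60 and 3.29.

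**Figure D4:**
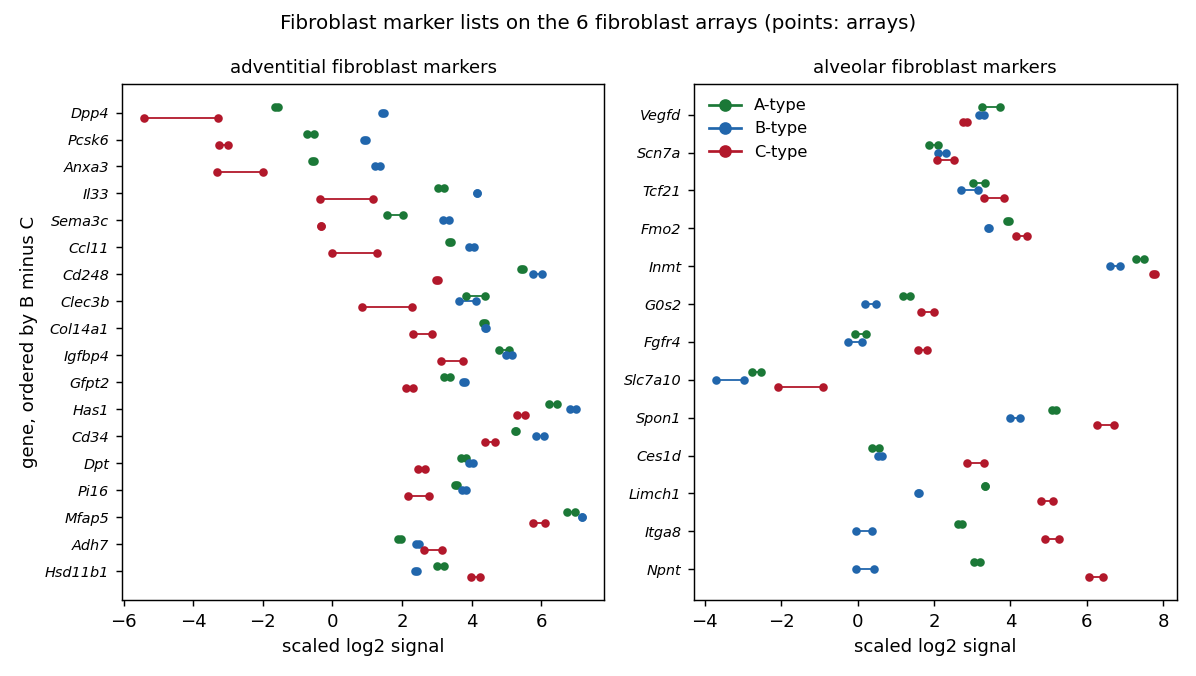
Scaled log2 signal (horizontal axes) of the tested adventitial and alveolar fibroblast markers (vertical axes, ordered by B minus C) on the 6 fibroblast arrays; points are arrays and lines join both arrays of a type. From B to C, 8 adventitial markers were called lower and Hsd11b1 higher, and 6 alveolar markers were called higher, with Npnt at mean levels of 0.19 in B, 3.13 in A and 6.24 in C.

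Myofibroblast and peribronchial markers were higher in B than in C (adjusted p = 0.000811; adjusted p = 0.102 with an estimated correlation), with 3 of 10 called and 4 over the list alone, such as Tgfbi at 4.59-fold and Aspn at 4.07-fold. Chemokines were higher (adjusted p = 0.00145; adjusted p = 0.192 with an estimated correlation), with 3 of 18 called higher, including Ccl11 at 10.3-fold (3.37; 4.01 without C1, 2.72 without C2), and Cxcl14 called lower at 7.56-fold. Over the list alone 8 were higher and 2 lower. Wnt genes were higher (adjusted p = 0.00433; adjusted p = 0.102 with an estimated correlation), with 3 of 14 called, Sfrp4 at 15.4-fold, Sfrp2 at 6.21-fold and Wnt2b at 4.49-fold, and 7 higher and 2 lower over the list alone. Complement genes were higher (adjusted p = 0.028; adjusted p = 0.296 with an estimated correlation), with Cfb at 4.63-fold and Cd55 at 3.71-fold called among 10 (2 higher and 1 lower over the list alone), and did not pass without C1 (adjusted p = 0.0812) or under quantile scaling (0.0641). Among lists that did not pass, called members included Tbx2, Tbx4 and Foxf2, transcription factor genes of the lung mesenchyme, lower in B by 6.37-fold, 4.15-fold and 4.24-fold, and Aldh1a1, lower at 9.06-fold, beside Aldh1a2, higher at 17.1-fold (5.10 without C1, 3.10 without C2).

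Alveolar type 2 markers were lower in B than in C as a list (adjusted p = 0.0157; adjusted p = 0.223 with an estimated correlation), with Sftpc called among 9 (-3.58 ± 0.61, adjusted p = 0.0341; -2.65 without C1, -4.51 without C2) and 3 lower over the list alone. The list did not pass without Pu1, Pu2 or B1 (highest adjusted p = 0.0839). T and NK markers were lower by the list test (adjusted p = 0.0454; adjusted p = 0.289 with an estimated correlation), with 0 of 11 called and 1 over the list alone, and did not pass without Pu1, Pu2, B1 or C1 (highest adjusted p = 0.206), nor under quantile (0.0725) or median scaling (0.0554). These stand beside the fibroblast lists above. Of the 62 named genes called between B and C, 60 lost their call without B1, 49 without B2, 22 without C2, 6 without C1 and 20 without A1 or without A2. The count of genes was 186 without A1 or without A2, 2 without B1, 16 without B2, 921 without C1, 233 without C2 and 817 without Pu1 or without Pu2. With the 6 fibroblast arrays alone, which between types is the same fit as without Pu1 or without Pu2, 817 passed. With the 4 compared arrays alone 133 passed.

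Genes higher in C than in each of the other types numbered 20, and 0 genes were higher in A or in B than in each of the others. With array weights limma gave 4 in A and 58 in B, and normexp gave 9 in B. Leading the C set were Upk1b, Chd7, Sytl2, Tcim, Dach1, Npnt, Adgrg6 and Mtss1. Dach1, a transcription cofactor gene, was 8.85-fold above A and 11.3-fold above B, and Mtss1, a membrane-shaping protein gene, was 8.31-fold and 25.2-fold above them. The set held 0 genes without A1, A2, B1, B2 or C2, 92 without C1 and 79 without Pu1 or without Pu2.

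Among lists that did not pass, the median, the mean and the test differed in sign for lymphatic, alveolar type 2, alveolar type 1, basement membrane, complement, Wnt and proliferation genes between A and B. They differed for the sorting panel's positive and lineage markers, blood endothelial, B cell, retinoid, mesenchymal transcription factor and immediate early genes between A and C, and for lineage, mesothelial, elastic fibre, retinoid and mesenchymal transcription factor genes between B and C.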

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

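The tests of B-type cells and of unsorted lung cells in the first C-type sample, both tests of alveolar type 2 signal and the test of the pooled spread were chosen only after the results were seen.

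Probes without a gene name also carried signal. Among the results above, only the count from the fit of every probe includes them. Of 13681 such probes tested in that fit, 919 were brighter and 1669 dimmer in the 3 fibroblast types than in pulmonary single cells.

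The C-type arrays differed at least 2-fold in 20.8% of genes, against 5.19% for the A type and 5.49% for the B type. Weaker signal on C2 is argued against among the brightest genes and stays open among dimmer ones. Among the 4414 brightest genes, where background weighs least, 3.92% differed at least 2-fold between C1 and C2. The share was 0% between the A arrays and 0.0453% between the B arrays. A bound set in advance against weaker signal, a C share at least 2 times the larger of these, was met. These genes were a single set for all groups, so some may be dim on C2. The A and B shares were also lower here than over all genes, so the fall from 20.8% does not decide the question for dimmer genes. C2 also had the lowest share of spots well above background, 54.6%. Unsorted lung cells in the C1 sample are argued against. The 660 genes at least 16-fold brighter in pulmonary cells than on C2 rose on C1 by a median of 0.28 (upper quartile 1.43). The 21% share that Ly6a would need calls for 3.25 (Thy1 would need 49.1%). B-type cells in C1 cannot be told apart from other causes: 118 genes at least 16-fold brighter in B than on C2 rose by a median of 2.56, above the 1.29 that a 6.09% share needs, which is the share for Ly6a while Thy1 would need 12.1%, yet 12 of them, among them Efhd1 (-3.62 on C1 against -0.06 needed), stayed over 2-fold below their needed level, and genes picked for low values on C2 rise by selection (0.49 in the reverse set of 42 genes). The limit on how many genes may stay below was added after these values were seen, and a difference in how the C-type samples were prepared or gated stays open and untested.

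Of the alveolar type 2 markers, the 6 measured on both C-type arrays, not all of which were measured in A and B, were brighter in C than in the mean of A and B by a median of 1.205. A general admixture of lung cells large enough to raise whole lists is argued against. The airway list had a median of -0.29 (upper quartile 0.38) and the macrophage list one of 0.0038 in the same difference. A small share cannot be excluded this way, because members near background would not show it. Single members went both ways in A minus C, with Lyz2 at -1.71 and Scgb1a1 at -1.48 against Cyp2f2 at 4.87 and H2-Ab1 at 1.32, none of them called. Type 2 cells or their RNA in the C-type sort stay open: 5 of these 6 were brighter in C, from 3.05 for Sftpc down to 0.12 for Lamp3, and Abca3 was not (-0.49), although its level in A and B would hide a small share. Sorting against E-cadherin would remove epithelial cells but not free RNA, and C minus pulmonary differences of the measured members lay between -6.48 and -0.64. Expression of these genes by C-type fibroblasts themselves was not tested.

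Limma called 0 genes between the A and B types, with 573 at an unadjusted p under 0.05 where chance alone gives 883. The spread shared with the pulmonary and C-type arrays may hide differences, since with the 4 A and B arrays alone 1948 genes reached an unadjusted p under 0.05. Whether chance gives as many cannot be settled with 3 splits, which allow no share under 0.05: the real split gave 1948 and the highest other 687. A bound on the other splits set in advance was met by 687, but it was wrong, because 3 splits cannot exclude chance at that level. Genes far apart did not pass either, such as Efhd1 at 8.42-fold (adjusted p = 0.225) and Thy1 at 33.4-fold (adjusted p = 0.257). Thy1 read -0.455 and -0.033 on the A-type arrays against 4.959 and 4.675 on the B-type arrays. It passed with array weights (adjusted p = 0.0069) and normexp (0.0405), so 0 calls do not show that the types are alike. THY-1 was among the antibodies of the sort, so Thy1 is not independent of how the types were separated.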

How the results depend on the processing

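The fit on the 6 fibroblast arrays alone and the list tests with one array left out were chosen only after the data were seen. The alternatives were followed for the named genes that passed in a comparison and for the sorting panel genes, lineage markers between types aside. Their directions held in each alternative that tested them, with the exceptions given here, while counts of calls moved. Directions of other named values, such as Npnt between A and B, were not checked across the alternatives. The stricter filter and the fits on fewer groups tested only part of these genes and comparisons. The cause was not tested for any count below unless the construction of the alternative is named. With array weights, which give the pulmonary arrays 0.291 and the B-type arrays 2.56, 3103 genes passed between fibroblasts and pulmonary cells, 3120 for A, 3389 for B and 2143 for C against pulmonary cells, 244 between A and B, 220 between A and C and 743 between B and C, and the sets higher in A, B and C held 4, 58 and 70. With normexp, 21 passed between A and B and 178 between A and C, and the sets of B and C held 9 and 67. With trended robust variance the counts were 4 between A and B, 138 between A and C and 47 in the C set. Without the filter on dim probes, where more genes are tested, they were 1 between A and C, 249 between B and C and 0 in the C set. In the test of every probe a gene may count several times, and probes without a gene name count too. It gave 10264 between fibroblasts and pulmonary cells, 7851 between C and pulmonary cells, 28 between A and C and 9 in the C set. The mean of a gene's probes gave 34 in the C set and quantile scaling gave 12. List calls were followed in the mean-of-types comparison and between types, and not for each type against pulmonary cells. Of these, median scaling ended myofibroblast markers between A and B (camera adjusted p = 0.0642) and T and NK markers between B and C (0.0554). It added positive markers between A and B (0.0481). Quantile scaling ended myofibroblast markers between A and B (0.0698), complement genes between A and C (0.0742) and B and C (0.0641) and T and NK markers between B and C (0.0725), and added immediate early genes between B and C (0.0226). With only the compared arrays, which leaves 2 residual degrees of freedom, 2265 passed between C and pulmonary cells, 0 between A and C, 133 between B and C and 0 in the C set. The 6 fibroblast arrays alone gave 229 between A and C, 817 between B and C and 79 in the C set. For gene calls between types this fit equals those without Pu1 or without Pu2. Likewise, leaving out either array of a group outside a comparison gives the same gene calls, since the lone array adds nothing to the spread.

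With each array left out in turn, the lone array of a group being assumed to vary like the other groups, counts ranged from 4623 to 7705 between fibroblasts and pulmonary cells, from 2157 to 6902 for A, 2346 to 7127 for B and 3683 to 6394 for C against pulmonary cells, from 0 to 483 between A and C, from 2 to 921 between B and C and from 0 to 92 in the C set, and stayed at 0 between A and B and in the sets of A and B. Of the 26 lists called between fibroblasts and pulmonary cells, 0 lost their call with any array left out.

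Under median scaling and in the authors' table, the sign turned for Ly6a between fibroblasts and pulmonary cells (0.29 and 0.29; 0.02 without Pu2, 0.33 without C2, and lowest at -0.46 without C1) and for Mcam between fibroblasts and pulmonary cells (0.0921 and 0.0933), A and pulmonary cells (0.10 and 0.10), B and pulmonary cells (0.0415 and 0.04) and C and pulmonary cells (0.14 and 0.14); both scalings add a constant per array. With the mean of a gene's probes Mcam passed as lower in all 4 (adjusted p = 0.00104, 0.003, 0.00205 and 0.00749), on a mean that includes a probe above background on 0 fibroblast arrays. Rarb turned between fibroblasts and pulmonary cells with normexp (0.51) and with the mean of a gene's probes (0.20), and Thy1 between A and C turned without C1 (1.31, against -2.13 without C2). None of these values but that of Rarb was past the threshold to begin with, and the cause was not tested.

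The labels do not state whether equal replicate numbers mark a shared animal, day or preparation. Deviations of same-numbered arrays correlated at -0.085 to 0.058 over 6 pairs of groups, so no large effect shared by number was seen. A smaller shared effect cannot be excluded by these correlations. With the replicate number as a block, 0 genes passed between A and C and 0 in the C set, and 304 passed between B and C. The list of myofibroblast markers between A and B lost its call (camera adjusted p = 0.0702). The block changed no other list call between types or in the mean-of-types comparison. List calls of each type against pulmonary cells were not run with the block. A model with slide as a block could not be fitted, because slide and the pulmonary group coincide. On C2 54.6% of spots were well above background, the lowest share of the 8 arrays.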

Other observations

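The groups of genes in this part were chosen only after the values were seen. None was tested as a list. Of the tested homeobox genes, which mark position along the body axis, 5 of 9 Hoxa and 5 of 7 Hoxb genes were higher in the sorted fibroblasts than in pulmonary single cells, with Hoxa3 at 2.53 ± 0.27 (adjusted p = 0.000512), Hoxb4 at 3.11 ± 0.30 (adjusted p = 0.000344) and Hoxb7, above background on 1 pulmonary array, at 3.81 ± 0.55 (adjusted p = 0.00196; 2.85 with the floor). The others did not pass, among them Hoxb9 (-0.55), Hoxa13 (-0.33) and Hoxa9, above background on 1 of 6 fibroblast arrays. In the Hoxc cluster 1 of 3 was higher, Hoxc4, above background on 1 pulmonary array, and in the Hoxd cluster 2 of 2 were lower, Hoxd12 (-0.88) and Hoxd13 (-1.92 ± 0.45, or -1.81 with the floor), which was above background on 2 of 6 fibroblast arrays. Between B and C, 0 of these genes were called by limma.

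Of 11 Ly6 genes looked at, 5 were lower in C than in B, the SCA-1 gene Ly6a and Ly6a2, Ly6c1, Ly6f and Ly6g, with Ly6c1 at a B minus C of 4.57 ± 0.46 (adjusted p = 0.00599), while Ly6d, Ly6e, Ly6h, Ly6i, Ly6k and Ly6m did not pass (B minus C of -0.67, 1.03, -0.17, 1.65, 1.70 and 0.22). Ly6c1 had mean levels of 5.67 in the pulmonary cells, 6.85 in A, 7.39 in B and 2.82 in C. Its C-type arrays differed, as its A minus C values without C1 and without C2 above show. Probes of this family share sequence, and cross-hybridisation between them was not tested.

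With array weights, where 244 genes passed between A and B, the called genes measured on both arrays of both types included Npnt at 7.68-fold, Gja5 at 7.46-fold and Plekha7 at 7.2-fold higher in A, and Thy1 at 33.4-fold, Esm1, which encodes the proteoglycan endocan, at 12.2-fold and Efhd1 at 8.42-fold higher in B. They passed in that alternative and not in the fit reported above.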
